A study of Anser cygnoides with 6 samples.

How the data were processed

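The series holds droplet-based single-cell RNA sequencing of testis cells from swan geese (Anser cygnoides), with 3 samples from birds of high sperm motility and 3 from birds of low sperm motility. Per the labels' protocols, testis tissue was cut up and digested with collagenase, papain and DNase, red blood cells were lysed, dead cells were removed on magnetic columns, and the suspension was loaded for a target of 8000 cells per sample. The deposited values are whole-number UMI counts per gene and barcode, made by the authors with Cell Ranger 9.0.1, per the submitters' processing notes, which also name bcl2fastq 5.0.1. The counts are not normalised, and the genome build and annotation are not given in the sources used here, so no coordinates are printed. Of the 25511 features, 11429 carry LOC identifiers, and 25133 names matched the RefSeq gene table of the Taihu_goose_T2T_genome assembly, which was used only for names, gene neighbours and, without regard to strand, whether genes overlap. The labels do not say whether each sample came from a separate bird, so p-values measure only the spread between these samples, which may be partly technical. No pair of samples agreed within sampling noise (chi-square per degree of freedom between 126 and 477).

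The tests, cell filter, clustering settings, marker lists, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, and no barcode exceeded the mitochondrial limit. Mitochondrial UMIs were nearly absent from the counts (median share per sample between 0.0% and 0.134%), so this limit was no check on damaged cells. Doublets were scored per sample with Scrublet in scanpy 1.11.5, and the highest-scoring cells were removed at 0.8% per 1000 barcodes, which came to between 7.17% and 11.3% per sample. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used without integration, and cells were clustered with 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), which gave 31 clusters of 57304 cells.

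Clusters were named from markers of 16 cell types fixed beforehand, and each name ends in "-like" because it rests on markers alone. The scoring rule was settled after the clusters had been seen. For each class it took the mean log2 fold of the markers over the median cluster, with a pseudocount of 0.1, and required a mean of at least 0.6, at least 3 markers at 2-fold or more, a lead of 10% over the next class, and no other class with more markers among the 10 leading genes. Sertoli-like clusters also needed SOX9 in 10% of cells. A cluster without a class was left unnamed, and unnamed cells made up 3.76% of the high-motility and 1.80% of the low-motility cells. These were cluster 14 (1717 cells, led by SPARC and AMH beside spermatid transcripts), cluster 29 (65 cells with AMH and FOXL2, all from low-motility sample 2) and cluster 30 (34 cells, from the same sample). Only 8 of the 28 elongating spermatid markers and 16 of the 26 round spermatid markers were annotated. No cluster was named Leydig-like or peritubular myoid-like, so the Leydig-like comparison planned beforehand was not made.

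Raw UMI counts were summed per sample over all kept cells and over each class with at least 20 cells in at least 2 samples per group. Sums were compared between the motility groups with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood test), with Benjamini-Hochberg adjustment within a fit and a threshold of 0.05. All log2 fold changes are high minus low motility, and the standard error given with each is the fold change divided by the square root of the F statistic. The macrophage-like fit used 3 high- and 2 low-motility samples, since low-motility sample 1 held 13 such cells. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over all 175 tests of a list in a class, and lists needed at least 5 tested members. The 24 lists cover dynein arms and their assembly, radial spokes and central pair, doublet microtubule inner proteins and tektins, intraflagellar transport, sperm ion channels, the acrosome, meiotic recombination, steroidogenesis, cholesterol, hormones and growth factors, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, the citrate cycle, fatty acid oxidation, retinoids, antioxidant defence, tubule junctions, extracellular matrix, heat shock and dissociation stress, apoptosis, interferon and antigen presentation, cytosolic ribosomal proteins, and haemoglobin. The mitochondrially encoded list had too few tested members in every class. The level of a list in a sample is the mean of log2(CPM + 1) over its members. The difference of the motility effect between germ cells and named somatic cells was tested with limma on per-sample log2 CPM differences. Cell shares and depth per cell were compared with exact two-sided permutation tests over 20 assignments, whose smallest possible p is 0.1.

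Named genes were the 5 of smallest p in each fit, since no gene passed edgeR's test, together with markers named in advance for each class (KIT and STRA8, SYCP3, axonemal and sperm genes, and Sertoli cell genes). PRM1, CATSPER1 and LHCGR were not annotated, and GDNF was not tested in Sertoli-like cells. One gene that the rule names in Sertoli-like cells is not reported here. List members given as examples, and any other gene named in the text, were chosen after their values were seen. On simulated counts drawn from these samples, the edgeR test recovered 23.1% of 4-fold changes in whole samples (19359 genes), 89.7% in spermatogonia-like (9685), 69.5% in spermatocyte-like (16514), 13.6% in round spermatid-like (15433), 2.88% in elongating spermatid-like (12798), 7.02% in spermatid-like (16180), 52.0% in Sertoli-like (12464) and 24.6% in macrophage-like sums (4351). The germ cell against somatic test recovered 0 of 180 such changes (12999 genes). Germ and somatic counts were drawn independently there, so spread shared by both within a sample could not cancel. The recovered share may therefore be too low for that test. At 16-fold the recovered share was between 45.5% and 98.8%, and between 3.90% and 8.65% of the calls were false.

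Alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each sample in turn, cell filters of none and of 1000 genes, no doublet removal, scaling within each sample before clustering, Leiden resolution 0.5, shares within germ or somatic cells, edgeR on cell counts, camera with an estimated correlation, and fry. Other alternatives were added after seeing the data. The first used a split of the samples by number of barcodes (over or under 12000) as a term or as a batch. The second compared high-motility sample 1 alone with the low-motility samples, because 42 genes had far lower counts in high-motility samples 2 and 3, and the third left those genes out of the lists, which by its construction favours higher values in high motility, so no call gained there is reported. Where an arm held 1 sample, that sample was assumed to vary like the other group. Free RNA was not removed. AMH, a Sertoli cell hormone, had a UMI in 95.8% of Sertoli-like cells (median 1194 UMIs per cell) and in 20.4% of round spermatid-like cells (median 5391.5), and ODF1, a sperm tail gene, in 91.8% of elongating spermatid-like (median 4182.5) and 24.0% of Sertoli-like cells. The share of cells with a UMI of a gene is therefore given beside the share for the same gene in a class that should lack it, and is not read as expression at or below that share.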

Results

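Testis cells were profiled in 3 samples from geese of high sperm motility and 3 from geese of low sperm motility, to ask whether hormonal and metabolic support from somatic cells and genes of the sperm axoneme differ with motility. The high-motility samples held 12114, 9070 and 13757 barcodes with 65776772, 49726472 and 51565775 UMIs (samples 1, 2 and 3), and the low-motility samples 9028, 14121 and 8965 barcodes with 66908686, 73384483 and 54378193 UMIs, beside a stated target of 8000 cells. After the cell filter and doublet removal, 10510, 7706 and 10950 high-motility and 8246, 11718 and 8174 low-motility cells remained. The median kept cell had 3687 ± 1087 UMIs (SD, n = 3) in high-motility and 4800 ± 992 in low-motility samples, and 1899 ± 501 against 2416 ± 388 genes (exact permutation p = 0.3 for both). The UMI difference of -1113 was -486 without high-motility sample 3, -630.3 without low-motility sample 1 and -409 with at least 1000 genes per cell, and the difference in genes of -517 was -239.8 without high-motility sample 3 and -272 with that filter. Samples also differed in number of barcodes, with high-motility samples 1 and 3 and low-motility sample 2 above 12000 and the others below, and values within these 2 sets of samples are given where a comparison rests on them.

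The germ cell series from spermatogonia to elongating spermatids made up most of each suspension, and Sertoli cells, which nurse the germ cells, were the main somatic class. Round and elongating spermatid-like cells together made up 46.8 ± 8.81% of high-motility and 61.3 ± 17.9% of low-motility cells (SD, n = 3 each; exact permutation p = 0.3). Sertoli-like cells made up 22.0 ± 4.53% and 14.6 ± 16.4% (exact p = 0.5), and spermatocyte-like cells, which are in meiosis, 20.6 ± 3.62% and 20.2 ± 4.43% (exact p = 0.8). Macrophage-like cells, marked by CSF1R, CD74 and C1Q genes, were 0.96 ± 0.30% of high-motility and 0.23 ± 0.10% of low-motility cells, and all 3 high-motility samples lay above all 3 low-motility samples (exact p = 0.1, adjusted p = 0.533; chance separates 10% of classes in this way). The cluster so named also held CD3E, a T cell gene, with a UMI in 20.2% of its cells, beside 21.7% for CSF1R and 22.0% for C1QC. With at least 1000 genes per cell the macrophage-like difference was 0.27 percentage points instead of 0.74, and as a share of somatic cells it was 0.64 points (exact p = 0.8).

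Spermatogonia-like cells made up 5.21 ± 6.53% against 1.88 ± 0.71% (exact p = 0.8), where high-motility sample 1 alone held 12.7%. Without that sample the difference changed sign, to -0.44 percentage points, and so did the spermatocyte-like difference (-1.66 points, and -0.80 and -0.94 without low-motility sample 1 or 2). Endothelial-like cells made up 0.62 ± 0.51% against 0.13 ± 0.14% (exact p = 0.2), and the difference of 0.49 points was 0.21 without high-motility sample 3, which held 1.19%, and 0.32 with at least 1000 genes per cell. The Sertoli-like difference of 7.49 points was 17.0 without low-motility sample 2, and 3.16, 2.34 and 4.93 without low-motility sample 1 or 3 or high-motility sample 3. It was 12.7 points with no filter on genes per cell and 2.30 with at least 1000. The spermatid-like difference of -14.4 points was -24.6 without low-motility sample 2, -7.78 without low-motility sample 1 and -8.16 with at least 1000 genes per cell, and the spermatocyte-like difference of 0.41 was 2.14 with no gene filter and 4.72 at Leiden resolution 0.5. With 3 samples against 3, no share could pass 0.05 in the exact permutation test. Within the samples of more and of fewer barcodes, the macrophage-like difference was 0.65 and 0.98 percentage points, the Sertoli-like difference was -10.7 and 15.4 points, and the spermatid-like difference was 0.83 and -14.5 points. An edgeR test on cell counts per class gave the macrophage-like class a log2 ratio of 2.09 (adjusted p = 0.0467). The tissue was dissociated and passed through dead cell columns, which can set these shares.

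**Figure D1:**
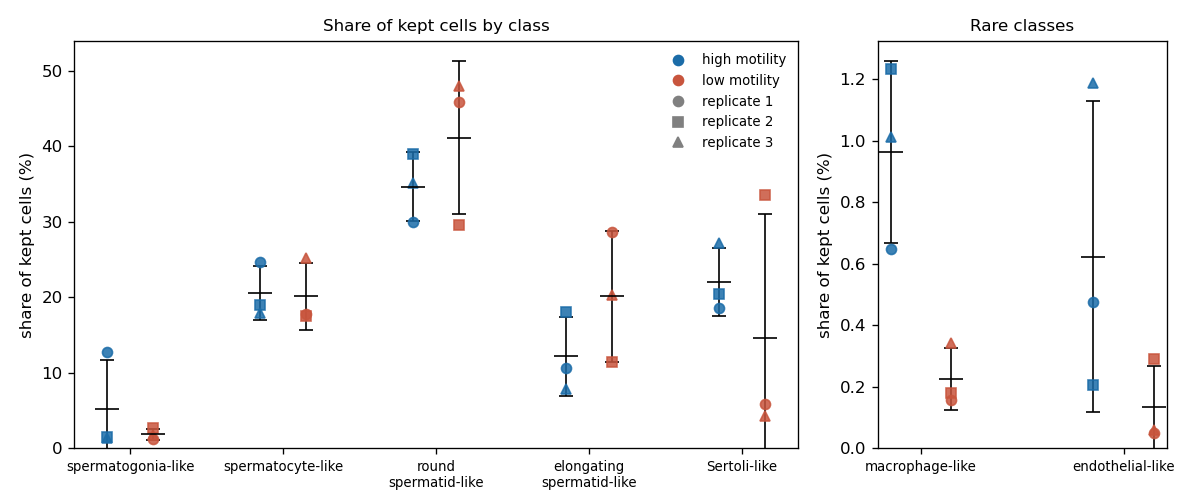
Share of kept cells (%) in each class per sample (points), with the mean and SD of each motility group (n = 3; SD bars are not drawn below 0). Macrophage-like shares of the 3 high-motility samples, 0.96 ± 0.30%, lie above those of the 3 low-motility samples, 0.23 ± 0.10%, whereas the other classes overlap or spread widely.

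Over all cells of a sample, the gene of smallest p was LOC106036569, a long non-coding RNA, with 7, 1 and 5 UMIs in the high-motility samples and 3741, 513 and 1552 in the low-motility samples (log2 fold change -8.62 ± 1.06, SE; adjusted p = 0.965, edgeR). The other genes of smallest p were LOC136790470 (3.41 ± 0.51), LOC106031513 (2.46 ± 0.47), LOC136786830 (3.73 ± 0.74) and LOC106041707 (-2.18 ± 0.44), none of which passed. edgeR called 0 of 19614 genes, with 811 at unadjusted p under 0.05, and DESeq2 called 46 (24 higher and 22 lower). The groups did not overlap in 9.25% of genes, where chance gives 10%. Set alone against the low-motility samples, high-motility sample 1 also gave 0 of 20664 genes (773 at unadjusted p under 0.05).

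In spermatogonia-like cells, the genes of smallest p were FABP7, a fatty acid binding protein (-1.63 ± 0.30), CARHSP1, an RNA-binding protein (1.36 ± 0.28), RNPEP, an aminopeptidase (-2.01 ± 0.43), SS18L2 (0.93 ± 0.21) and CDH9, a cadherin (-1.71 ± 0.38), and none passed (adjusted p = 0.942, edgeR). KIT, the receptor of differentiating spermatogonia, differed by -0.18 ± 0.26, and STRA8, which acts at the start of meiosis, by -0.49 ± 0.57, and the sign for KIT changed with 1 sample left out. edgeR called 0 of 9981 genes, with 419 at unadjusted p under 0.05, and DESeq2 called 0. Groups did not overlap in 10.7% of genes. Without high-motility sample 1, edgeR called 179 genes, 173 of them lower in the high-motility samples, and 29 of the 179 were among the 42 genes with far lower counts in high-motility samples 2 and 3. That sample alone against the low-motility samples gave 4 calls, IRX4 and LOC136786389 lower and IGLL1 and STAG3 higher.

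In spermatocyte-like cells, LOC136790470 (3.67 ± 0.48, adjusted p = 0.763, edgeR), MTFMT, which formylates the mitochondrial initiator tRNA (1.06 ± 0.19), LOC106036569 (-3.80 ± 0.69), LOC106045298 (-1.65 ± 0.31) and LOC106033728 (-2.57 ± 0.49) had the smallest p. SYCP3, a core protein of the synaptonemal complex, differed by 0.34 ± 0.25. edgeR called 0 of 16790 genes, with 850 at unadjusted p under 0.05, DESeq2 called 14, and groups did not overlap in 10.8%. Without high-motility sample 1, edgeR called 144 genes (141 lower in high motility, 32 of the 144 among the same 42 genes). Of these, 71 were also called in spermatogonia-like cells. That sample alone gave 0 (907 at unadjusted p under 0.05).

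Spermatids build the flagellum, and the axonemal genes fixed for them mostly differed by less than their errors or near them. HYDIN in round spermatid-like cells (-0.61 ± 0.42) lay further out. In the round and elongating classes together, DNAI1, an outer dynein arm chain, differed by -0.037 ± 0.40, DNAH1, an inner arm heavy chain, by -0.032 ± 0.42, TEKT1, a tektin, by 0.32 ± 0.35, and SPAG6 and HYDIN, both of the central apparatus, by 0.17 ± 0.39 and -0.50 ± 0.46. ODF1, an outer dense fibre protein, differed by 0.22 ± 0.35. Round spermatid-like cells alone gave -0.06 ± 0.36 for DNAI1, -0.17 ± 0.38 for DNAH1, 0.32 ± 0.33 for TEKT1, 0.13 ± 0.33 for SPAG6, -0.61 ± 0.42 for HYDIN and 0.33 ± 0.34 for ODF1. Elongating spermatid-like cells gave -0.30 ± 0.50, 0.38 ± 0.54, 0.0031 ± 0.52, -0.026 ± 0.56, -0.33 ± 0.50 and -0.11 ± 0.40 for the same genes in that order. None passed edgeR's adjustment. The signs of DNAI1, DNAH1, TEKT1, SPAG6 and ODF1 depended on the scaling, the clustering or the samples kept.

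The genes of smallest p in spermatid-like cells were LOC106036569 (0, 0 and 1 UMI in high-motility and 3658, 466 and 1504 in low-motility samples; adjusted p = 0.140, edgeR), LOC136790162 (-4.06 ± 0.69), LOC136790470 (3.31 ± 0.60), LOC106046431 (-3.74 ± 0.80) and NHERF1, a membrane scaffold (2.14 ± 0.46). Round spermatid-like cells gave LOC106036569 (adjusted p = 0.146), LOC136790162 (-4.00 ± 0.71), PCDH17, a protocadherin (3.28 ± 0.60), ATOH1, a transcription factor (-4.27 ± 0.86), and LOC136790470 (3.17 ± 0.66). Elongating spermatid-like cells gave LOC106036569, without a UMI in the high-motility samples, LOC136790162 (-4.14 ± 0.75), STAG3, a meiotic cohesin (2.93 ± 0.64), LOC136786551 (-2.29 ± 0.51) and FES, a tyrosine kinase (-4.08 ± 0.94). edgeR called 0 genes in each, of 16564, 15929 and 13217, with 526, 596 and 427 at unadjusted p under 0.05, and DESeq2 called 45, 51 and 3. Groups did not overlap in 7.81%, 9.08% and 7.64% of genes. Clusters within these classes were held by different samples, such as round clusters 11 (low-motility sample 1), 8 (low-motility 2), 7 and 16 (high-motility 3) and 19 (high-motility 1), and elongating clusters 12, 22 and 23 (low-motility 1, low-motility 2 and high-motility 3). With high-motility sample 1 alone, edgeR called 0 in all 3 fits (373, 391 and 445 at unadjusted p under 0.05).

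In Sertoli-like cells, AMH, FSHR and INHA, the hormone and hormone receptor genes named in advance, differed by less than 2 standard errors. AMH, anti-Müllerian hormone, differed by 0.51 ± 0.28, FSHR, the follicle-stimulating hormone receptor, by -0.41 ± 0.37, INHA, the inhibin alpha chain, by 0.036 ± 0.39, and SOX9, the Sertoli cell transcription factor, by -0.057 ± 0.30. CLU, which encodes the secreted chaperone clusterin, differed by 0.85 ± 0.40. The signs of FSHR, INHA and SOX9 changed with 1 sample left out, and SOX9 was at 1.09 with no filter on genes per cell (adjusted p = 0.261, edgeR) and at 0.24 with scaling within each sample. Of the 40 tested genes of the hormone list, 18 were higher and 22 lower, and 0 passed edgeR's test over all genes (2 higher and 1 lower at unadjusted p under 0.05). Among the genes of smallest p were MAP9, a microtubule-associated protein (-1.12 ± 0.21), XKR4 (-1.71 ± 0.33), VWA1, a matrix protein (1.48 ± 0.29), and NHERF1 (2.01 ± 0.42), and none passed (adjusted p = 0.681, edgeR). edgeR called 0 of 12928 genes, with 940 at unadjusted p under 0.05. DESeq2 called 5, which were XKR4, MAP9, VWA1, LETM2 and LOC125181435. Of these, LETM2 was among the 42 genes with far lower counts in high-motility samples 2 and 3. Groups did not overlap in 14.7% of genes. The class was held by different clusters, 1 (high-motility 1 and low-motility 2), 6 (high-motility 3), 17 and 28 (high-motility 2), 25 (high-motility 1), 18 (mainly low-motility 2) and 24 (low-motility 1 and 3). Without high-motility sample 1, edgeR called 9 genes, all lower in high motility and 8 of them among the 42 genes with far lower counts in high-motility samples 2 and 3. That sample alone gave 0 (626 at unadjusted p under 0.05).

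In macrophage-like cells, the genes of smallest p were LOC136786953 (3.28 ± 0.66), PRDX1, a peroxiredoxin (2.10 ± 0.45), CD7, a surface protein of lymphocytes (3.97 ± 0.90), SYNE2 and TNFSF13B, the last 2 without counts in the 2 low-motility samples used (adjusted p = 0.995 for the class, edgeR). edgeR called 0 of 4775 genes, with 182 at unadjusted p under 0.05, and DESeq2 called 1, LOC136786953. Without a filter on low counts edgeR called 3, LOC136786953, LOC125181435 and TNFSF13B. With high-motility sample 1 alone, edgeR singled out CTSC (log2 difference 2.54), GPNMB (9.59), LOC106038139 (8.33), CLU (2.75), IGFBP7 (4.05) and CTSD (3.03), all higher. CLU was a Sertoli marker fixed beforehand, and IGFBP7 led Sertoli-like cluster 1, which held 1432 cells of that sample. AMH had a UMI in 26.5% of macrophage-like cells, and free RNA was not removed. Free RNA of Sertoli-like cells was therefore not told apart for CLU and IGFBP7. CD3E, a T cell gene, had a UMI in 20.2% of macrophage-like cells (median 1510.5 UMIs per cell), in 0.44% of elongating spermatid-like cells (median 4182.5) and in 4.98% of spermatocyte-like cells (median 6953).

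Among the gene lists, cytosolic ribosomal protein genes rose together in high-motility samples in whole samples and in each tested class except spermatogonia-like cells. None of these calls held with a correlation estimated from the data (adjusted p = 0.865 in macrophage-like cells and 0.857 elsewhere with an estimated correlation). The rise was largest in Sertoli-like cells, where 69 of 69 members were higher with a median log2 difference of 0.66 (adjusted p = 1.92e-25, camera), such as RPS12 (0.81 ± 0.22). In elongating spermatid-like cells 67 members were higher and 3 lower (median 0.52, adjusted p = 8.23e-13), in round 68 and 2 (0.43, 1.24e-12), in both together 68 and 2 (0.45, 4.35e-12), in spermatocyte-like 68 and 2 (0.29, 2.40e-13), in macrophage-like 68 and 1 (0.56, 1.09e-09) and in whole samples 67 and 3 (0.37, 1.06e-11). In spermatogonia-like cells the list level differed by 0.05 (exact permutation p = 0.7). All 3 high-motility samples lay above all 3 low-motility samples in list level in whole samples and in spermatocyte-like, round, elongating and Sertoli-like cells (exact p = 0.1, the smallest possible), and the difference in whole samples was 0.39 and 0.40 within samples of more and of fewer barcodes. In Sertoli-like cells it was 0.99 and 0.51, in spermatocyte-like 0.33 and 0.30, in round 0.24 and 0.45, in elongating 0.40 and 0.41, and in both together 0.24 and 0.49. The median was 0.36 in macrophage-like cells without high-motility sample 3, and 0.29 in all spermatid-like cells without low-motility sample 3. High-motility sample 1 alone gave a median of 0.77 in Sertoli-like cells and 0.25 in whole samples, and lost the call in macrophage-like cells.

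**Figure D2:**
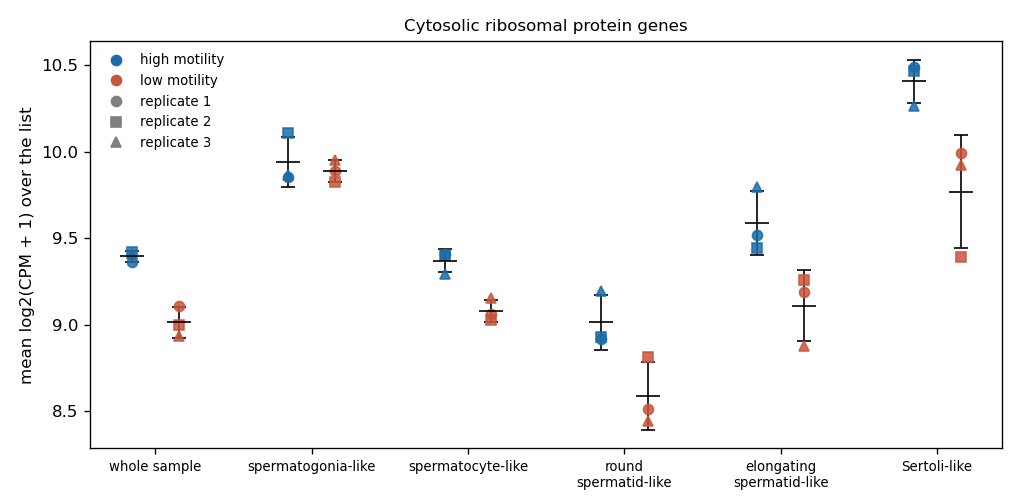
Mean log2(CPM + 1) of the cytosolic ribosomal protein genes per sample (points), with the mean and SD of each motility group (n = 3), in whole samples and 5 classes. The high-motility samples lie above the low-motility samples in each pair of columns except spermatogonia-like cells, where the means differ by 0.05.

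Heat shock and dissociation stress genes rose in high-motility samples in whole samples and in each tested class except macrophage-like cells (adjusted p = 0.716). The list calls did not hold with an estimated correlation (adjusted p = 0.857 with an estimated correlation). In round spermatid-like cells 28 members were higher and 2 lower (median 0.82, adjusted p = 1.54e-10), in elongating 26 and 3 (1.11, 3.32e-08), in both together 29 and 2 (0.73, 2.59e-10), in spermatocyte-like 26 and 7 (0.19, 0.000337), in spermatogonia-like 19 and 5 (0.26, 0.00145), in Sertoli-like 27 and 9 (0.28, 0.0309) and in whole samples 34 and 5 (0.63, 8.29e-09). Of the members, 0 passed over all genes. Adjusted over the list alone, 5 passed in round spermatid-like cells, namely DDIT3 (3.79 ± 0.82) and GADD45B (2.29 ± 0.62), both induced by stress, FOS (3.07 ± 0.70) and BTG2 (2.67 ± 0.60), both immediate early genes, and HSPB1, a small heat shock protein (1.40 ± 0.35; adjusted p between 0.0222 and 0.0355). The same 5 passed adjusted over the list alone in spermatid-like cells (0.0398). In elongating spermatid-like cells high-motility sample 3 had a list level of 7.63, and the other 5 samples lay between 4.51 and 5.36. Of the 893 cells of elongating cluster 23, led by genes that included ID2 and GADD45B, 841 came from that sample. It held 863 elongating spermatid-like cells in all, so its elongating values rest on that cluster, whose raised markers did not include ODF1. At Leiden resolution 0.5 the sample held 31 elongating spermatid-like cells. Without high-motility sample 3 the medians were 0.35 in round, 0.25 in elongating, 0.38 in all spermatid-like and 0.0039 in spermatocyte-like cells and 0.33 in whole samples, all still past the threshold. The Sertoli-like call was lost without that sample (adjusted p = 0.224), without low-motility sample 1 (0.0886) or 3 (0.0507) and with the split by barcodes as a term (0.0631), and the spermatogonia-like call was lost without low-motility sample 3 (0.0507). Both were lost with high-motility sample 1 alone (0.394 and 0.386). With the barcode term the medians were 0.38 in whole samples and 0.41, 0.68 and 0.076 in round, elongating and spermatocyte-like cells. Other samples moved medians that still passed. Without high-motility sample 1 the median was 0.41 in spermatogonia-like and 0.36 in spermatocyte-like cells, and without high-motility sample 2 it was 1.38 in both round and all spermatid-like cells. Without low-motility sample 2 it was 0.96 in whole samples and 0.44 in spermatocyte-like cells, and without low-motility sample 3 it was 0.54 in round and 0.093 in spermatocyte-like cells. Within samples of more and of fewer barcodes the list level differed by 0.48 and 0.37 in whole samples, 0.98 and 0.39 in round, 1.23 and 0.37 in elongating, 1.01 and 0.38 in both together, 0.25 and 0.17 in spermatocyte-like, 0.17 and 0.48 in spermatogonia-like and 0.27 and 0.20 in Sertoli-like cells. Over all samples its exact permutation p was 0.1 in round, spermatocyte-like, spermatogonia-like and Sertoli-like cells, where the groups did not overlap, and 0.2 in whole samples, elongating and all spermatid-like cells, where they did.

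Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain, rose in high-motility Sertoli-like cells, where 58 members were higher and 17 lower (median 0.28, adjusted p = 0.000134), such as SDHC (0.81 ± 0.24) and NDUFA6 (0.72 ± 0.22). Neither this call nor those in the other classes held with an estimated correlation (adjusted p = 0.857 with an estimated correlation). They rose too in round spermatid-like cells (58 and 18, median 0.30, adjusted p = 0.000773), elongating spermatid-like cells (54 and 21, 0.22, 0.0224) and both together (58 and 18, 0.29, 0.00257). In spermatocyte-like cells the test and the median were positive (54 and 22, 0.20, 0.00135), whereas the mean was -0.029. The members COX5A (-1.05 ± 0.80) and NDUFAB1 (-1.51 ± 1.18) in spermatocyte-like cells were among the 42 genes with far lower counts in high-motility samples 2 and 3. The Sertoli-like call was lost without low-motility sample 2 (0.0587). The spermatocyte-like call was lost without high-motility sample 1 (0.195) or low-motility sample 3 (0.0606), and the round call without high-motility sample 3 (0.0640) or low-motility sample 3 (0.0763). The elongating call was lost without high-motility sample 1 (0.297), high-motility sample 3 (0.117) or low-motility sample 3 (0.381), and the joint spermatid call without the same samples (0.0656, 0.0749 and 0.192). With the split by barcodes as a term, the calls in the 3 spermatid fits were lost (0.0535, 0.152 and 0.0761 for round, elongating and both together). The list level differed within samples of more and of fewer barcodes by 0.28 and 0.11 in Sertoli-like, 0.088 and 0.025 in round, 0.065 and -0.049 in elongating, 0.065 and 0.046 in all spermatid-like and 0.017 and -0.031 in spermatocyte-like cells. Over all samples the levels of the groups overlapped in each of these classes (exact permutation p = 0.6 in Sertoli-like, 0.4 in round, 0.7 in elongating, 0.4 in all spermatid-like and 1.0 in spermatocyte-like cells).

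Other lists of metabolism and protection rose in Sertoli-like cells. Citrate cycle genes were higher for 18 members and lower for 4 (median 0.36, adjusted p = 0.00175), such as SUCLG1 (0.71 ± 0.22), and the call was lost with an estimated correlation (adjusted p = 0.857 with an estimated correlation). Antioxidant genes were higher for 24 and lower for 6 (0.33, 0.00533), with CAT, catalase, at 0.96 ± 0.22 and SOD1 at 0.99 ± 0.25, whereas HMOX1, which degrades haem, was at -1.89 ± 0.55. With an estimated correlation, adjusted p was 0.857 for the antioxidant list here and in whole samples. The antioxidant list also rose in whole samples (26 and 7, 0.32, 0.00183), with TXN2 at 1.09 ± 0.29. Levels differed within samples of more and of fewer barcodes by 0.40 and 0.37 for the citrate list, by 0.34 and 0.31 for the antioxidant list in Sertoli-like cells, and by 0.087 and 0.43 for the latter in whole samples. The exact permutation p of these levels was 0.1, 0.2 and 0.1 in the same order. The antioxidant calls were lost without low-motility sample 2 in Sertoli-like cells (0.0981) and without low-motility sample 3 in whole samples (0.0536), and the Sertoli-like median was 0.20 without high-motility sample 2. Adjusted over the list alone, PRDX1 (2.10 ± 0.45) and GPX3 (2.92 ± 0.81) passed in macrophage-like cells (0.0160 and 0.0464), where 0 passed over all genes and the list itself did not pass. GPX3 was among the leading genes of Sertoli-like cluster 6, and AMH had a UMI in 26.5% of macrophage-like cells. Free RNA of Sertoli-like cells was therefore not told apart for GPX3.

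Of the lists of the axoneme, dynein arm genes and radial spoke and central pair genes fell in whole high-motility samples, which held fewer spermatid-like cells on average (46.8% against 61.3%). Within samples of more and of fewer barcodes, that share differed by 0.83 and -14.5 points. The dynein arm list was lower for 34 members and higher for 15 (median -0.17, adjusted p = 0.0190; adjusted p = 0.865 with an estimated correlation). Lower members included DNALI1 (-1.51 ± 0.60) and DRC1, a gene of the dynein regulatory complex also on that list (-0.96 ± 0.27). Radial spoke and central pair genes were lower for 27 and higher for 3 (-0.24, 0.00374; adjusted p = 0.857 with an estimated correlation), such as RSPH9 (-0.77 ± 0.33). Doublet microtubule proteins and tektins (13 higher and 30 lower, -0.11, adjusted p = 0.115) and intraflagellar transport genes (17 and 21, -0.038, 0.223) did not pass. Without high-motility sample 1 both calls were lost (0.796 and 0.551), the dynein call was also lost without low-motility sample 2 (0.0813), and both were lost with the split by barcodes as a term (0.0639 and 0.0631). Medians without high-motility sample 3 were -0.29 for dynein arms and -0.39 for radial spokes, and -0.38 for the latter without low-motility sample 2. List levels differed by -0.23 and -0.13 for dynein arms and by -0.20 and -0.18 for radial spokes within samples of more and of fewer barcodes (exact permutation p = 0.1 and 0.2 over all samples). Within spermatid-like cells the dynein list had 26 members higher and 22 lower (median 0.021, mean -0.031, adjusted p = 0.967) and the radial spoke list 12 and 18 (-0.068, 0.657). Doublet microtubule proteins and tektins had 30 members higher and 13 lower there (0.19, 0.291). High-motility sample 1 alone against the low-motility samples gave lower values in spermatid-like cells for radial spokes (median -0.25). It also did in elongating spermatid-like cells for doublet microtubule proteins (-0.39). Neither list passed in these classes with all samples.

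The dynein arm, radial spoke and doublet microtubule lists fell in macrophage-like cells, where the sperm tail gene ODF1 had a UMI in 30.1% of cells (median 1510.5 UMIs), against 91.8% of elongating spermatid-like cells (median 4182.5). Adjusted p was 0.857, 0.857 and 0.886 with an estimated correlation. Dynein arm genes there were lower for 29 and higher for 7 (median -0.36, adjusted p = 0.000541), radial spokes for 15 and 2 (-0.64, 0.000541) and doublet microtubule proteins for 30 and 9 (-0.22, 0.0290). Without low-motility sample 3 all of these were lost (0.104, 0.340 and 0.788), and the doublet microtubule call was lost without high-motility sample 1 (0.366) or 3 (0.535). Medians were -0.78 for dynein arms and -0.60 for doublet microtubule proteins without high-motility sample 2, -0.19 for dynein arms and -0.39 for radial spokes without high-motility sample 3, and -0.42 for doublet microtubule proteins without low-motility sample 2.

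Acrosome and gamete fusion genes rose in round spermatid-like cells (16 higher and 1 lower, median 0.27, adjusted p = 0.00632) and in all spermatid-like cells (14 and 3, 0.30, 0.0285), such as ACR, the acrosomal protease acrosin, at 0.95 ± 0.37 in the round class. Both calls were lost with an estimated correlation (adjusted p = 0.857 with an estimated correlation). The round call was lost without high-motility sample 2 (0.0563) or 3 (0.172), without low-motility sample 3 (0.0509), with the split by barcodes as a term (0.0517) and with high-motility sample 1 alone (0.819). The joint call was lost without high-motility sample 2 (0.173) or 3 (0.246), or low-motility sample 1 (0.134) or 3 (0.147), and with the split by barcodes (0.103), and with high-motility sample 1 alone its median turned to -0.054 (0.963). Without low-motility sample 2 the medians were 0.50 in round and 0.55 in all spermatid-like cells. The list level differed by 0.14 and 0.52 in round and by 0.033 and 0.55 in all spermatid-like cells within samples of more and of fewer barcodes (exact permutation p = 0.2 for both over all samples). Cholesterol synthesis and uptake genes rose in elongating spermatid-like cells (16 and 7, 0.33, 0.0399), a call that was lost with an estimated correlation (adjusted p = 0.857 with an estimated correlation). It was also lost without high-motility sample 3 (0.841), low-motility sample 1 (0.0650), 2 (0.0763) or 3 (0.127), with the split by barcodes (0.246), and with high-motility sample 1 alone (0.441). Its median was 0.61 without high-motility sample 2, and its level differed by 0.47 and -0.072 within samples of more and of fewer barcodes (exact permutation p = 0.4 over all samples). INSIG1, a regulator of sterol synthesis, passed adjusted over the list alone in macrophage-like cells (1.84 ± 0.52, adjusted p = 0.0300), where 0 passed over all genes.

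Interferon and antigen presentation genes rose in whole high-motility samples (16 higher and 6 lower, median 0.97, adjusted p = 0.000134), with CD74, the invariant chain, at 2.17 ± 0.53, IRF8 at 1.29 ± 0.43 and B2M at 1.06 ± 0.41. This call was lost with an estimated correlation (adjusted p = 0.857 with an estimated correlation). Macrophage-like cells were 0.96% of high-motility and 0.23% of low-motility cells. The list level differed by -0.0022 within the samples of more barcodes and by 0.87 within those of fewer (exact permutation p = 0.2 over all samples), and the median was 0.64 without low-motility sample 1. Within spermatogonia-like cells RSAD2, an antiviral gene, passed adjusted over the list alone (2.91 ± 0.69, adjusted p = 0.0169), where 0 passed over all genes. Tubule junction genes rose in whole samples (27 and 6, 0.38, 0.0221), with CLDN11, a tight junction protein of Sertoli cells, at 1.25 ± 0.57, where Sertoli-like cells were 22.0% and 14.6% of cells. That call was lost with an estimated correlation (adjusted p = 0.865 with an estimated correlation). The junction call was lost without high-motility sample 1 (0.165) or 3 (0.128), without low-motility sample 1 (0.358) or 3 (0.127), and with the split by barcodes (0.411). Its median was 0.64 without high-motility sample 2 and 0.70 without low-motility sample 2, and its level differed by -0.088 and 0.35 within samples of more and of fewer barcodes (exact permutation p = 0.4 over all samples).

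The remaining lists passed in no class. Hormones, receptors and growth factors had their smallest adjusted p at 0.213 in whole samples and 0.767 in Sertoli-like cells, and steroidogenesis at 0.184 in macrophage-like and 0.730 in Sertoli-like cells. The smallest adjusted p was 0.267 for glycolysis, 0.291 for fatty acid oxidation, 0.234 for retinoids, 0.136 for intraflagellar transport, 0.374 for sperm ion channels, 0.0860 for meiotic recombination, 0.0860 for apoptosis, 0.435 for extracellular matrix and 0.501 for haemoglobin. In all, 32 of 175 tests of a list passed camera with the preset correlation (27 higher, 5 lower), 0 with an estimated correlation (3 at unadjusted p under 0.05) and 0 with fry (smallest adjusted p 0.224, 12 at unadjusted p under 0.05). Without low-motility sample 3 the number was 18, and high-motility sample 1 alone gave 44 (27 higher, 17 lower).

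The difference between high and low motility was compared between germ cells and somatic cells of the same samples. The gene of smallest p was LOC106041452 (log2 difference of 1.94, germ minus somatic), followed by LOC106046821 (-1.63), DOK7, which acts at the nerve-muscle synapse (1.45), LOC106038172 (-1.60) and SLIT1, a guidance cue (-1.60), and none passed (adjusted p = 0.976 for the first 4, limma). limma called 0 of 13396 genes, with 559 at unadjusted p under 0.05, and no other tool was run. Without low-motility sample 1 it called 1, LOC106038449 (-4.70, adjusted p = 0.0112, limma), which was named after its value was seen. With high-motility sample 1 alone limma called 0 (442 at unadjusted p under 0.05).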

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

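The comparisons that used the split by number of barcodes, high-motility sample 1 alone, lists without the 42 genes far lower in high-motility samples 2 and 3, or RLE factors for the lists were chosen only after the results were seen. For most results the direction and the side of the threshold did not move, although for some of them one or the other could not move. This held for 64 of 75 class counts, 8 of 9 whole-sample counts, 580 of 636 values of single genes and 66 of 79 share differences over the settings other than leaving out 1 sample, among which counts and lists include high-motility sample 1 alone and shares include differences within the samples of more or of fewer barcodes. Not counting fry, under which 0 lists passed, 102 of 152 values of passing lists still passed under these settings. With 1 sample left out or with the 42 genes left out of the lists, 180 of 220 did. Leaving out the 42 genes favours higher values in high motility by construction. The exact permutation test of shares cannot pass the threshold, so outside edgeR on cell counts only the direction of a share could move. Share differences within the samples of more or of fewer barcodes had no test. Class and whole-sample counts without calls have no direction. The single genes include those of smallest p in the same fits, so the kept signs of such genes are not support. The depth per cell, in UMIs and in genes, kept its direction with both other cell filters and with each sample left out. For each changed count or sign below, the cause was not tested. The spread between samples limits small changes, since 4-fold changes were recovered in 2.88% of elongating spermatid-like and 89.7% of spermatogonia-like simulations, where the biological coefficient of variation was 0.614 and 0.256. Depth was not varied in the simulations.

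DESeq2 called 46 genes in whole samples, 14 in spermatocyte-like, 51 in round, 3 in elongating, 45 in all spermatid-like, 5 in Sertoli-like and 1 in macrophage-like cells, where edgeR called 0. Without a filter on low counts edgeR called 1, 1 and 3 in round, all spermatid-like and macrophage-like cells. High-motility sample 1 alone gave 4 in spermatogonia-like and 6 in macrophage-like cells, and put the acrosome list in spermatid-like cells at -0.054. Camera with an estimated correlation called 0 lists and fry 0. edgeR on cell counts gave macrophage-like cells a log2 ratio of 2.09, past the threshold. With the replicate number as a block, edgeR called 0 genes in whole samples and each class, limma 0, and camera 26 of 155 list tests, where the whole-sample dynein call (adjusted p = 0.0522) and the oxidative phosphorylation call in elongating cells (0.104) were lost. Samples of the same number did not deviate together in whole samples (correlations -0.085, -0.499 and -0.303) or in spermatid-like cells (0.189, -0.484 and -0.413), so the numbers were not taken as pairs. With the barcode term camera called 23 of 155 list tests, and with RLE factors 32 of 175. The block was not run for macrophage-like cells, nor was the filter of 1000 genes for that class.

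With 1 sample left out in turn, calls ranged from 0 to 179 in spermatogonia-like, 0 to 144 in spermatocyte-like and 0 to 9 in Sertoli-like cells, list tests from 18 to 42, and germ cell against somatic calls from 0 to 1. Differences in share ranged from -1.66 to 2.97 points for spermatocyte-like, -0.44 to 5.22 for spermatogonia-like and -0.27 to 3.53 for unnamed cells. Log2 differences in elongating spermatid-like cells ranged from -0.52 to 0.14 for ODF1, -0.48 to 0.42 for SPAG6 and -0.70 to 0.30 for TEKT1. In round spermatid-like cells they ranged from -0.32 to 0.17 for DNAH1, -0.26 to 0.24 for DNAI1 and -0.10 to 0.47 for SPAG6, and in both together from -0.26 to 0.26 for DNAH1, -0.30 to 0.22 for DNAI1, -0.022 to 0.45 for ODF1 and -0.14 to 0.49 for SPAG6. FSHR ranged from -0.72 to 0.091, INHA from -0.52 to 0.28 and SOX9 from -0.29 to 0.099 in Sertoli-like cells, and KIT from -0.37 to 0.20 in spermatogonia-like cells.

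Shares changed sign for unnamed cells with no gene filter (-0.97 points), scaling within samples (-2.63) and resolution 0.5 (-0.18). Spermatocyte-like cells changed sign with no doublet removal (-0.43) and scaling within samples (-7.50), round spermatid-like cells with scaling within samples (3.08) and Sertoli-like cells as a share of somatic cells (-2.12). Within samples of fewer barcodes the spermatogonia-like difference was -0.040 and the spermatocyte-like difference -2.50, and within those of more barcodes the round, all spermatid-like and Sertoli-like differences were 2.99, 0.83 and -10.7.

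No named gene passed under a setting that turned its sign. RLE factors and DESeq2 put DNAI1 in round cells at 0.017 and SPAG6 in elongating cells at 0.016. Without a filter on low counts TEKT1 in elongating cells was at -0.023 and SOX9 at 0.0059, and with the replicate block TEKT1 was at -0.20 and INHA at -0.10. With no gene filter DNAI1 in round cells was at 0.0031, SPAG6 in elongating cells at 0.17 and SOX9 at 1.09. With 1000 genes SPAG6 and ODF1 in elongating cells were at 0.037 and 0.043 and DNAH1 in spermatid-like cells at 0.020, and with no doublet removal DNAI1 in round cells was at 0.0028. Scaling within samples put DNAH1, TEKT1, SPAG6 and ODF1 at 0.31, -0.14, -0.069 and -0.23 in round cells and at 0.37, -0.10, -0.063 and -0.25 in all spermatid-like cells, SPAG6 and ODF1 at 0.094 and 0.065 in elongating cells, and SOX9 at 0.24. Resolution 0.5 put KIT at 0.052, and the barcode term put SOX9 at 0.15.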

Other observations

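Apart from the tests of shared barcodes, overlapping genes and free RNA, the tests in this part, counts of splits included, were chosen only after the result was seen. Although no cluster was named Leydig-like, Sertoli-like cells held UMIs of some genes known from steroid hormone cells above the shares in other classes. HSD3B1, which makes steroid hormone precursors, had a UMI in 31.4% of the 11257 Sertoli-like cells (median 1194 UMIs per cell), HSD17B3, which makes testosterone, in 29.0%, and INSL3, a hormone of Leydig cells, in 14.96%. In macrophage-like cells (median 1510.5 UMIs) these shares were 2.98%, 2.38% and 0.60%, and in round spermatid-like cells (median 5391.5) 1.93%, 1.25% and 0.70%. STAR and CYP11A1, which act first in steroid synthesis, had a UMI in 0.12% and 0.41% of Sertoli-like cells, and CYP17A1, which makes androgen precursors, in 0.37%, against 4.12% of spermatocyte-like cells (median 6953). Between high and low motility, HSD3B1 differed in Sertoli-like cells by 0.074 ± 0.24, HSD17B3 by 0.090 ± 0.28 and INSL3 by 0.43 ± 0.73 (log2, SE; none passed edgeR's adjustment). Cells with UMIs of 2 or more of STAR, CYP11A1 and CYP17A1 numbered 5, 6 and 8 in the high-motility and 1, 2 and 4 in the low-motility samples.

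In whole-sample sums, a set of 42 genes, of 8082 judged, had counts at least 4-fold lower in high-motility samples 2 and 3 than in the lowest of the other 4 samples, and the next of all 15 pairs, high-motility 3 with low-motility 2, had 22, although within round and elongating spermatid-like cells that pair had more such genes (74 against 44, and 137 against 46). The set included PDCD2 (3697, 299.6 and 501 CPM in high-motility and 4454, 3348 and 3997 CPM in low-motility samples), and ATP5IF1, COX5A, NDUFAB1, MRPL36 and COA3 of the mitochondria. Differing shares of the classes are argued against, since 82.05% of the 39 set genes judged in spermatocyte-like cells were as far lower there. Reads shared with an overlapping gene are argued against too, as 23.8% of the set overlapped another gene and 38.9% of the others did (ratio 0.612, Fisher's exact p = 0.0557), as far as the RefSeq table, read without strand, matches the annotation used for counting, and so is another barcode list, with 1.08 times the shared barcodes across as among the other 4 samples. A difference in counting or library handling, or a sequence variant between birds, stays open and was not tested.

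The higher ribosomal protein levels in high-motility samples may be technical or biological. The smallest gap between a high- and a low-motility sample of one set by barcodes was 0.31 in whole samples (SD within groups 0.066). In Sertoli-like cells it was 0.48 (SD 0.25). The groups were already known not to overlap there, so this gap could not have been 0 or lower and is no separate test. It shows only that the rise was present within both sets. In spermatid-like cells that gap was 0.081 against an SD of 0.20, which keeps the split by barcodes open there. Differing shares of the classes are argued against as the whole cause, since the list differed by 0.29 (SD 0.065) within spermatocyte-like cells. That class was picked after its difference was known, and within spermatogonia-like cells the list differed by 0.05. The spermatocyte-like value cannot exclude a differing mix of cells within that class. Its cluster 13 held 338, 379 and 649 high-motility and 175, 246 and 133 low-motility cells. Such a mix, dissociation and a biological difference tied to sperm motility stay open and were not tested.

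The split by number of barcodes, high-motility 1 and 3 with low-motility 2 against the others, gave 139 edgeR calls in whole samples, where motility gave 0, which points to a structure of the samples, with genes such as ASB12 (-3.34, more minus fewer barcodes). Within round spermatid-like cells 20.6% of 15929 genes had an unadjusted p under 0.05 (edgeR, 0 calls). These were 3288 genes, the most of any split, and the next split had 1457. They argue against class sizes alone, but cannot exclude a differing mix of cells within the class. Free RNA of Sertoli-like cells is argued against as the whole cause, since 30.7% of 1968 genes higher in spermatids had such a p within spermatid-like cells. There 21.75% of 3173 genes higher in Sertoli-like cells had one too, which leaves this free RNA open as a part of the cause. Within Sertoli-like cells 27.1% of genes higher in spermatids and 7.49% of genes higher in Sertoli-like cells had such a p. This leaves free RNA of spermatids open in that class. Spermatid-like cells made up 40.6%, 43.0% and 41.0% of high-motility samples 1 and 3 and low-motility sample 2, which had more barcodes. In high-motility sample 2 and low-motility samples 1 and 3 they made up 56.9%, 74.5% and 68.3%. The number of barcodes may itself reflect cell makeup, and a shared day, bird age or loading stays open and was not tested.

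LOC106036569, nearly without counts in the high-motility samples, had 7 tested neighbours with a median log2 difference of -0.21, between -1.37 and 1.22, in spermatid-like cells. The lowest was COBL, directly beside it, at 14.8, 13.3 and 24.7 CPM in high-motility and 47.9, 42.7 and 46.3 CPM in low-motility samples (unadjusted p = 0.0104, edgeR). The nearest genes on the other side were not tested.

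The 6 samples make 10 splits of 3 against 3, which cannot give a share under 0.05. The real split gave 0 calls in whole samples, where the highest of the others gave 139. With 0 calls in the real split all 10 splits give as many by construction, so that count decides nothing here, nor in spermatogonia-like (highest other 1), spermatocyte-like (2), round (0), elongating (0), all spermatid-like (8) and Sertoli-like cells (38), nor for germ against somatic cells (0), each with 0 calls in the real split. For gene lists over the classes run in every split, the real split gave 28 and the highest other 39, and 4 of 10 gave as many. The highest whole-sample and Sertoli-like counts came from the split by barcodes.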
